A study of Mus musculus with 6 samples.

How the data were processed

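RNA from whole testes of newborn male mice (postnatal day 0, FVB.129/Sv mixed strain) was measured on 1-colour (Cy3) Agilent arrays. There were 3 genotype groups with 2 animals each and 1 array per animal, and nothing was pooled. VSKO mice carry a Cre recombinase under the germ cell gene Ddx4 (also called Vasa), 1 deleted and 1 floxed Sin3a allele, so that germ cells lose both alleles. HEMI mice carry the same Cre with 1 deleted and 1 intact allele, and WT mice carry the Cre with both alleles intact. The series design text says that 2 biological replicate animals were used per condition. All 6 arrays lay on 1 slide, with 1 scan time and 1 protocol. VSKO and HEMI filled row 1 of the slide and WT lay in row 2, so slide row cannot be told apart from genotype in the comparisons with WT, while VSKO and HEMI shared a row.

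The deposited array files hold, for each of 62976 spots, the processed signal as an intensity on a linear scale, background-subtracted and detrended within its array, with surrogate values for spots not above background. They also hold the mean spot intensity and the local background intensity, and 0 or 1 flags for outlier, saturated and well-above-background spots, which per the file headers are quality calls and no measure of signal (unit: other). Per the file headers the extraction modules of Agilent Feature Extraction had version 10.7.3.1, and the authors' processing notes name version 8.5.1.1. The series table of the authors holds an intensity as well. Each of its values was checked to equal the processed signal divided by that array's median over 59305 non-control spots, within 0.001%. Probe positions are on the mouse build the array was designed on (mm9, NCBI37). Gene names were updated through a RefSeq table of assembly GRCm38.p6, used for names only. Of 55681 distinct probes, 26762 were matched through the accession of the probe, 102 through another accession, 3751 already had a symbol of that table and 25066 kept the name in the file. The name changed for 2930 probes.

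The log2 processed signal of each array was shifted by its 75th percentile over non-control spots, outlier spots were left out and the spots of 1 probe averaged. A probe was kept where it was well above background on both arrays of at least 1 group (34367 probes). Where a gene had several probes, the one with the highest mean over the 6 arrays was used, which left 24553 genes, those without a symbol included. Signal levels are given on this log2 scale, as mean ± SD of n = 2 animals. Differences between groups are given with the SE of the fit. The 6 arrays were fitted together with limma 3.58.1 in R 4.3.3 (1 mean per group, empirical Bayes without a trend, 3 residual degrees of freedom and 2.25 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method. A gene is said to rise, fall or change where the adjusted p was under 0.05. Counts at an unadjusted p under 0.05 are to be read against the 1228 of 24553 genes expected with no difference between groups. For a gene not well above background in 1 group, a lower bound of the fold is given, from the mean of the other group against the lowest signal that was well above background on the arrays of the dim group.

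The comparisons, the tests, the named genes and 29 gene lists were fixed before the data were examined. In each comparison the named genes are the 10 with the largest positive and the 10 with the largest negative difference among genes that passed with non-overlapping replicates, up to 4 passing members of each list, up to 4 leading members of each list that passed its own test, and 21 genes always given, of which Insl3 was not analysed here since no kept probe carries that name. Accessions, clone names and predicted genes were counted and not named. The lists are markers of germ cells in general, gonocytes and spermatogonial stem cells, Sertoli cells, fetal Leydig cells, interstitial progenitors and mesenchyme, peritubular myoid and smooth muscle, endothelium, macrophages, erythroid cells, mesonephric duct with epididymis and rete, skeletal muscle, adipocytes, peripheral glia and neurons, and granulosa and ovary pathway. The other lists are the SIN3 complex, piRNA pathway and transposon silencing, meiosis, haploid spermatid, niche signalling, G2/M cell cycle, DNA replication and S phase, p53 targets and apoptosis, interferon response, steroid and cholesterol synthesis, hypoxia and glycolysis, immediate early and heat shock, circadian clock, imprinted and ribosomal protein genes. Each was tested with camera of limma at a preset correlation of 0.01 and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted adjusted over the list alone.

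The overlap of comparisons that share arrays was set against 100 simulated data sets with no difference between groups. The fit was tested on simulated data, 20 runs per comparison with 200 of the genes changed: it called 17.2% to 18.6% of genes changed 2-fold, 84.8% to 86% of those changed 4-fold and 93.8% to 94.9% of those changed 8-fold, and 5.6% to 6.7% of its calls were false. Both kinds of simulation drew the noise of each gene independently, with no effect shared by genes, litters or slide rows. Their false calls and overlaps may therefore understate those of real arrays. Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the series table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the 4 arrays of the groups compared, replicate number as a block, a variance trend, a robust fit, array weights, other thresholds and leaving out each array in turn. Precision is limited by the number of arrays. Figures were drawn with matplotlib 3.10.9.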

Results

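Gene expression was measured in whole testes of newborn VSKO, HEMI and WT mice, with 2 animals and 2 arrays in each group. The 6 arrays gave 59.2% to 64.53% of their non-control spots well above background, with 0 saturated spots and 99 to 116 outlier spots per array. The 75th percentile of the processed signal ran from 652.2 to 857.1 before scaling. Pearson's r across genes between the animals of a group was 0.987 in VSKO, 0.989 in HEMI and 0.992 in WT. The first principal component held 36.7% of the variance and ran from the VSKO arrays (-42.9 and -38.3) through HEMI (-12.8 and 6.8) to WT (42.9 and 44.2).

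Sin3a, the scaffold protein of a histone deacetylase corepressor complex and the gene targeted in these mice, had a log2 signal of 0.50 ± 0.16 (SD, n = 2) in VSKO, 0.89 ± 0.00 in HEMI and 1.1 ± 0.01 in WT. The VSKO minus WT difference was -0.60 ± 0.13 (SE, limma adjusted p = 0.134), HEMI minus WT was -0.21 ± 0.13 (adjusted p = 0.568) and VSKO minus HEMI was -0.39 ± 0.13 (adjusted p = 0.522), so none passed. The 1 probe for Sin3a (gene ID 20466) lies on chromosome 9 from 56975655 to 56975714 and starts at base 4689 of its transcript. The exons deleted in these mice are not given in the sources used here, and where the probe lies outside them its signal checks nothing about the deletion. Sin3b, the paralogous scaffold, differed by 0.13 ± 0.13 between VSKO and WT (adjusted p = 0.690).

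The comparison of VSKO with WT asks what loss of both Sin3a alleles in germ cells does to the newborn testis. By the genotypes above, VSKO mice carry 1 deleted allele beside the floxed one, as HEMI mice do beside the intact one. Its loss in other cells of the testis may therefore be part of this comparison as well. Nanos2, an RNA-binding protein that holds male germ cells out of meiosis, fell by at least 7.14-fold, from a log2 signal of -3.12 ± 0.23 (SD, n = 2) in WT to -6.05 ± 0.61 in VSKO, where its probe was near background (adjusted p = 0.0426). Dnmt3l, a cofactor of de novo DNA methylation in germ cells, fell by 1.76 ± 0.18 (SE) on the log2 scale (adjusted p = 0.0314). The glycolytic enzymes Ldha, Pgk1 and Eno1 fell by 1.32, 1.01 and 0.94 (SE 0.12 to 0.13, adjusted p = 0.0307, 0.0430 and 0.0458), as did the collagen prolyl hydroxylase subunit P4ha1 by 1.41 (adjusted p = 0.0442). The array places its Pgk1 and Eno1 probes on chromosomes 3 and 2 and not at the genes themselves, so these probes may also measure processed copies. Cyp17a1, an androgen-making enzyme of Leydig cells, fell by 1.40 ± 0.16 (adjusted p = 0.0426), and Lhx1, a transcription factor of the mesonephric duct, rose by 1.25 ± 0.15 (adjusted p = 0.0433), while another, dimmer probe for Lhx1 stood at 0.27.

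In all, 237 of 24553 genes changed between VSKO and WT, 85 higher and 152 lower, and 143 of them carry a gene symbol. Probes that overlap in position put the 237 at 236 loci. For 68 of them the probe was near background in 1 of the groups, and so it was in WT for each of the 10 largest rises among genes with a symbol and non-overlapping replicates, probes without a symbol being left out of this ranking. These rises were at least 14.3-fold for Zfp874a, 9.52-fold for S100g, a calcium-binding protein, 6.93-fold for Ssty1, a spermiogenesis-specific transcript of the Y chromosome, 6.73-fold for the hair keratin-associated gene Krtap3-3 and 5.05-fold for Cacng2, a subunit that regulates AMPA receptors. The bounds hold for the probe used: another, dimmer probe for S100g stood at 2.83 on the log2 scale, short of its bound. The odorant receptor genes Olfr1318, Olfr429 and Olfr355 rose at least 3.40-fold, 3.28-fold and 3.1-fold, the homeobox gene Hoxb1 at least 3.32-fold and Iqcf4 at least 2.96-fold. Among the 10 largest falls ranked the same way, Platr26, a long non-coding RNA, fell by 4.65 ± 0.24 (SE) and Ctsh, a lysosomal protease, by 3.19 ± 0.28 on the log2 scale (adjusted p = 0.0142 and 0.0276). The other 8 were near background in VSKO: the interferon-inducible GTPase Gbp2b fell at least 8.67-fold, the zinc finger gene Mecom 7.60-fold, the retinyl ester synthase Lrat 7.27-fold, the uridine phosphorylase Upp2 6.99-fold, Fbxw26 4.61-fold, Olfr535 4.48-fold, Olfr1317 4.16-fold and the vomeronasal receptor gene Vmn1r132 2.10-fold. In HEMI against WT, Zfp874a stood at 4.81, Gbp2b at -4.27, Fbxw26 at -4.14, Ctsh at -2.95 and Lrat at -2.80, none passing there. Krtap3-3, Platr26, Mecom, Upp2, Olfr535 and Olfr1317 changed in HEMI too, so all of these set WT apart from both groups. S100g stood at 1.0 and Vmn1r132 at -0.16 in HEMI against WT, and the remaining rises at -0.49 to -0.29.

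Germ cell lists were lower in VSKO than in WT. Of 21 tested gonocyte and spermatogonial stem cell genes 1 fell (Nanos2), and adjusted over the list alone 5 fell and 1 rose, with a median of -0.16 (camera adjusted p = 0.0275, and adjusted p = 0.766 with an estimated correlation). Tspan8 stood at -1.44, Sall4, a zinc finger factor of stem cells, at -0.76 and Lin28b at -0.74, and Id4, the gene that rose adjusted over the list alone, at 0.64. Of 22 piRNA and transposon silencing genes 1 fell (Dnmt3l) and 5 fell adjusted over the list alone, among them Rnf17 (-1.42), Mov10l1 (-1.04) and Morc1 (-0.82), with a median of -0.27 (adjusted p = 0.00155, and adjusted p = 0.862 with an estimated correlation). None of 16 general germ cell genes passed over all genes, 4 fell (Stk31, Tdrkh, Rnf17 and Mov10l1) and 1, Tex19.1 at 1.01, rose adjusted over the list alone, and the median was -0.25 (adjusted p = 0.00454, and adjusted p = 0.944 with an estimated correlation). Without WT replicate 2 the call of the general germ cell list was lost (median -0.13, adjusted p = 0.161), as was that of the gonocyte list (-0.26, adjusted p = 0.157). Without VSKO replicate 2 the gonocyte list was not called either (-0.04, adjusted p = 0.229), nor with no filter on dim probes (adjusted p = 0.209) or with probes above background on all 6 arrays (adjusted p = 0.0740). Over the 18 alternatives at the preset correlation the adjusted p ran from 0.000154 to 0.161 for the general germ cell list and from 0.00291 to 0.229 for the gonocyte list.

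Lists of metabolism and of Leydig cells were lower as well. Of 19 tested hypoxia and glycolysis genes 4 fell and 10 fell adjusted over the list alone, with a median of -0.79 (camera adjusted p = 9.34e-08, and adjusted p = 0.221 with an estimated correlation). Fry gave an adjusted p of 0.0152 for that list. Of 20 steroid and cholesterol synthesis genes none passed over all genes and 4 fell adjusted over the list alone, Dhcr7 (-1.18), Fdps (-0.95), Sqle (-0.71) and Nsdhl (-0.65), with a median of -0.51 (adjusted p = 6.28e-07, and adjusted p = 0.862 with an estimated correlation). Of 16 fetal Leydig cell genes 1 fell (Cyp17a1) and 5 fell adjusted over the list alone, with Star, which carries cholesterol into mitochondria, at -1.83 and the side chain cleavage enzyme Cyp11a1 at -0.89. The Leydig cell median was -0.37 (adjusted p = 0.00155, and adjusted p = 0.766 with an estimated correlation), and -0.24 without VSKO replicate 1. Interferon response genes had a median of -0.39 over 19 genes (adjusted p = 0.00507, and adjusted p = 0.766 with an estimated correlation), of which none passed over all genes and 2, Isg15 (-1.21) and Rtp4 (-0.93), fell adjusted over the list alone. With no filter on dim probes the interferon list missed the threshold (adjusted p = 0.0505, lowest over the alternatives 0.000400).

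Other genes fixed in advance did not pass between VSKO and WT. Ddx4, the germ cell RNA helicase, differed by -0.24 ± 0.17 (SE, adjusted p = 0.569), Dazl by -0.31 (adjusted p = 0.491), Pou5f1 by -0.49 (adjusted p = 0.170), Zbtb16 by -0.52 (adjusted p = 0.262) and Piwil4 by -0.26 (adjusted p = 0.577). The Sertoli cell genes Sox9, Amh, Kitl and Gdnf differed by 0.21, -0.31, -0.17 and -0.35, and the chemokine Cxcl12 by -0.06. Acta2 of smooth muscle differed by 0.25, Pecam1 of endothelium by -0.23, the cell cycle inhibitor Cdkn1a by 0.62 and the proliferation marker Mki67 by 0.30.

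In 19 of the 29 lists no comparison passed the camera test, and their VSKO minus WT medians follow. The Sertoli cell list stood at -0.04 (adjusted p = 0.959), interstitial progenitors and mesenchyme at 0.06 (0.926), peritubular myoid and smooth muscle at 0.10 (0.374), endothelium at -0.19 (0.809), and granulosa and ovary pathway at -0.11 (0.990). Macrophage genes stood at 0.03 (0.704), skeletal muscle at -1.08 (0.263), adipocytes at -0.14 (0.483), and peripheral glia and neurons at -0.16 (0.517). Skeletal muscle genes differed within groups, with array medians of -1.38 and 0.07 in VSKO and 1.44 and -0.97 in WT. The SIN3 complex list stood at 0.04 (adjusted p = 0.583), meiosis at -0.11 (0.374), haploid spermatid at 0.18, or 0.09 with dim genes at their bound (0.517), and niche signalling at -0.15 (0.170). G2/M cell cycle genes stood at 0.12 (adjusted p = 0.0712), DNA replication and S phase at -0.16 (0.170), p53 targets and apoptosis at -0.06 (0.809), immediate early and heat shock at -0.04 (0.960), circadian clock at -0.02 (0.990) and imprinted genes at -0.11 (0.374). Erythroid genes at 0.38 (adjusted p = 0.344), mesonephric genes at 0.20 (0.263, with Lhx1 higher) and ribosomal protein genes at -0.07 (0.636) were not called in this comparison either.

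The count of 237 was 69 without VSKO replicate 1 (44 higher and 25 lower, 36 of them among the 237), 31 without VSKO replicate 2 (18 higher and 13 lower, 22 shared), 42 without either HEMI array (23 higher and 19 lower, 35 shared) and 0 by limma without either WT array, with 2619 and 2816 genes at an unadjusted p under 0.05 without WT replicate 1 and 2. No named gene that passed did so without a WT array, and Nanos2, Dnmt3l, Ldha, Pgk1, Eno1, P4ha1, Cyp17a1 and Lhx1 were among those that passed in none of the 6 fits. All 28 named genes that passed kept their direction, but this was fixed in advance. The replicates of each called gene did not overlap, so leaving out 1 array cannot turn its sign.

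**Figure D1:**
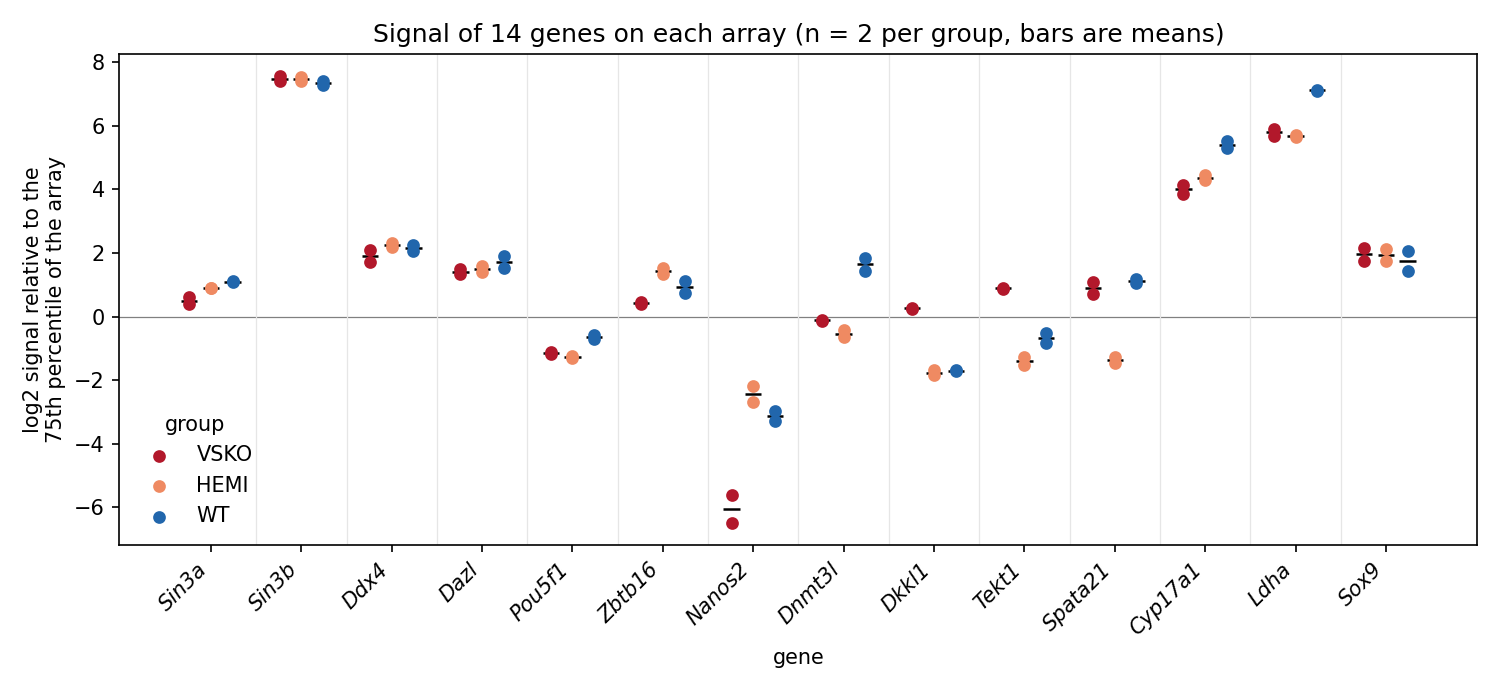
Log2 signal relative to the 75th percentile of each array (vertical axis) for 14 genes on the 6 arrays, with 1 point per array and a bar at the mean of the 2 animals of a group. Nanos2 is lowest in VSKO (-6.05), Dnmt3l (1.65) and Ldha (7.11) are highest in WT, and Dkkl1 (0.27) and Tekt1 (0.88) are highest in VSKO.

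The comparison of HEMI with WT asks what loss of 1 Sin3a allele does. Dnmt3l fell by 2.19 ± 0.18 (SE) on the log2 scale, from 1.65 ± 0.28 (SD, n = 2) in WT to -0.54 ± 0.16 in HEMI (adjusted p = 0.0428). Spata21, a spermatogenesis-associated gene, fell by 2.48 ± 0.18, Rbmy, a Y-linked RNA-binding gene of germ cells, by 1.94 ± 0.16, the neurokinin receptor Tacr3 by 2.00 ± 0.13 and the ubiquitin ligase Trim63 by 2.10 ± 0.16 (adjusted p = 0.0283 to 0.0438). Nanos2 stood at 0.69 ± 0.34 (adjusted p = 0.495).

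In all, 29 genes changed between HEMI and WT, 8 higher and 21 lower, and 16 of them carry a gene symbol. Krtap3-3, Vmn1r104, Ankdd1a and Olfr965, near background in WT, rose at least 7.10-fold, 2.03-fold, 1.39-fold and 1.22-fold. Platr26 fell by 4.46 ± 0.24 (SE) on the log2 scale (adjusted p = 0.0157). Mecom, Upp2, Olfr535 and Olfr1317, near background in HEMI, fell at least 6.86-fold, 6.31-fold, 4.04-fold and 3.75-fold. Among the other genes fixed in advance Ddx4 stood at 0.10, Dazl at -0.22, Pou5f1 at -0.63, Zbtb16 at 0.50, Piwil4 at -0.77, Star at -1.94, Cyp17a1 at -1.03, Amh at -0.43 and Cdkn1a at 0.40 (adjusted p = 0.120 to 0.840), while Sox9, Kitl, Gdnf, Cxcl12, Acta2, Pecam1, Mki67 and Sin3b lay between -0.39 and 0.20.

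Hypoxia and glycolysis genes were lower in HEMI too, with a median of -0.74 over 19 genes (camera adjusted p = 8.80e-10, and adjusted p = 0.159 with an estimated correlation). None of them passed over all genes and 11 fell adjusted over the list alone, among them P4ha1 (-1.50), Ldha (-1.43), Pgk1 (-1.18) and Eno1 (-1.02). Fry gave this list an adjusted p of 0.00411. Of 20 steroid and cholesterol synthesis genes 1, Fdps at -0.96, fell adjusted over the list alone, with a median of -0.40 (adjusted p = 3.43e-05, and adjusted p = 0.999 with an estimated correlation). The HEMI arrays stood apart in that list (-0.27 and 0.08), and without HEMI replicate 1 its median was -0.21. Of 16 fetal Leydig cell genes 5 fell adjusted over the list alone, with Cyp11a1 at -1.0 and Fdx1 at -0.87, and the median was -0.33 (adjusted p = 0.00120, and adjusted p = 0.999 with an estimated correlation). Without WT replicate 2 the adjusted p of the Leydig cell list was 0.0594 (range over the alternatives 3.54e-05 to 0.0594), and without HEMI replicate 1 its median was -0.52. General germ cell genes had a median of -0.24 (adjusted p = 0.0304, and adjusted p = 0.999 with an estimated correlation), with Rnf17 (-1.27) and Tdrkh (-0.92) lower adjusted over the list alone. That call was lost without either VSKO array (adjusted p = 0.0547), without HEMI replicate 1 (median -0.11, adjusted p = 0.336) and without WT replicate 2 (-0.07, adjusted p = 0.640), with a range of 0.00131 to 0.640 over the alternatives. It was also lost with median scaling or the series values (adjusted p = 0.0516), with normexp (0.0535) and with no filter on dim probes (0.116).

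Ribosomal protein genes lay lower in HEMI with a median of -0.18 over 20 genes (camera adjusted p = 0.0224, and adjusted p = 0.999 with an estimated correlation), and none passed alone: Rplp0 stood at -0.27, Rps6 at -0.26 and Rpl32 at -0.21. With quantile scaling their median was -0.02 (adjusted p = 0.876), with median scaling or the series values -0.15 (adjusted p = 0.0516), with no filter on dim probes -0.18 (adjusted p = 0.166), and the call was also lost without HEMI replicate 2 (adjusted p = 0.212), WT replicate 1 (0.0785) or WT replicate 2 (0.0682). Over the alternatives the adjusted p of the ribosomal list ran from 0.00262 to 0.876. Mesonephric duct, epididymis and rete genes had a median of 0.27 over 13 genes (adjusted p = 0.0304, and adjusted p = 0.999 with an estimated correlation), with 1, Lhx1 at 1.52, higher adjusted over the list alone (1.18 by its other probe), Krt8 at 0.51 and Epcam at 0.65. The HEMI arrays differed in this list, with medians of 0.70 and -0.43. Without HEMI replicate 1 the mesonephric median was -0.32 (adjusted p = 0.872), without HEMI replicate 2 it was 0.96, and without WT replicate 1 it was 0.32 (adjusted p = 0.146), as with quantile scaling (0.32, adjusted p = 0.05, which missed the threshold), with a range of 8.71e-07 to 0.872 over the alternatives. The piRNA list stood at -0.22 (adjusted p = 0.0631), gonocyte and spermatogonial stem cell genes at 0.06 (0.949), interferon response genes at 0.00 (0.949) and erythroid genes at -0.29 (0.437).

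The count of 29 was 4 without either VSKO array (1 of them among the 29) and 8 without HEMI replicate 1 (3 shared). It was 0 by limma without HEMI replicate 2, WT replicate 1 or WT replicate 2, with 2463, 2191 and 2393 genes at an unadjusted p under 0.05. Dnmt3l, Spata21, Rbmy, Tacr3, Trim63 and Platr26 were called in none of these 6 fits, and Upp2 was called in 1. They kept their direction, which their non-overlapping replicates fixed in advance.

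The comparison of VSKO with HEMI asks what loss of the second allele in germ cells adds, within 1 slide row. Tekt1, a tektin of cilia and sperm tails, rose by 2.28 ± 0.16 (SE) on the log2 scale, from -1.40 ± 0.17 (SD, n = 2) in HEMI to 0.88 ± 0.01 in VSKO (adjusted p = 0.0347). Dkkl1, an acrosomal protein of spermatids, rose by 2.03 ± 0.12 (adjusted p = 0.0197), Spata21 by 2.27 ± 0.18 (adjusted p = 0.0407) and Xkr6 by 2.30 ± 0.16 (adjusted p = 0.0347). Spata21 stood at -0.21 in VSKO against WT (adjusted p = 0.639). The zinc finger gene Sall1 fell by 1.72 ± 0.13 (adjusted p = 0.0364), with 1 of the VSKO arrays not well above background, so the size of this fall is uncertain. Nanos2 missed the threshold at -3.62 ± 0.34 (adjusted p = 0.0576), a difference of at least 11.5-fold. Every VSKO array lay below every HEMI array, but the arrays of these groups did not overlap in 32.9% of all genes, against 33.3% by chance. Zbtb16, a transcription factor of spermatogonial stem cells, stood at -1.01 ± 0.17 (adjusted p = 0.150).

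In all, 35 genes changed between VSKO and HEMI, 25 higher and 10 lower, and 24 of them carry a gene symbol. Probes that overlap in position put the 35 at 34 loci. Of the 25 higher genes 21 were also higher in VSKO than in WT, and Spata21, Tmem63c, Oas3 and Klf17, named after their values were seen, did not pass there. Ssty1, Cacng2, Olfr429, Olfr355, Iqcf4 and Hpcal4, near background in HEMI, rose at least 9.68-fold, 7.06-fold, 4.59-fold, 4.33-fold, 4.14-fold and 2.88-fold. The defensin gene Defb28, Vmn1r104, Msmp, Vmn1r132 and Olfr965, near background in VSKO, fell at least 4.99-fold, 3.14-fold, 2.36-fold, 1.88-fold and 1.88-fold. Vmn1r104 and Olfr965, near background in WT too, stood at only -0.44 and -0.46 in VSKO against WT, so HEMI stood apart there. HEMI against WT and VSKO against HEMI, which share the HEMI arrays, had 0 called genes in the same direction. They had 5 in opposite directions, with Vmn1r104, Olfr965 and Spata21 among them. Another, dimmer probe for Defb28 stood at -1.39 on the log2 scale, short of the bound of the probe used. Ddx4 stood at -0.34, Dazl at -0.09, Pou5f1 at 0.14, Dnmt3l at 0.43, Piwil4 at 0.52, Cyp17a1 at -0.36, Star at 0.11 and Cdkn1a at 0.22, none of which passed. Sox9, Amh, Kitl, Gdnf, Cxcl12, Acta2, Pecam1, Mki67 and Sin3b lay between -0.19 and 0.16.

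Interferon response genes were lower in VSKO than in HEMI, with a median of -0.32 over 19 genes (camera adjusted p = 0.000277, and adjusted p = 0.948 with an estimated correlation). None passed over all genes and 2, Rtp4 (-0.94) and Isg15 (-0.75), fell adjusted over the list alone, beside Usp18 (-0.56) and Irf7 (-0.48). Oas3, outside the list but of the same gene family as its member Oas1a, went the other way (1.59, limma adjusted p = 0.0484), with its probe near background in HEMI. Erythroid genes were higher with a median of 0.54 over 12 genes (adjusted p = 0.0372, and adjusted p = 0.948 with an estimated correlation), and none passed: the globin genes Hba-a1 and Hbb-bt stood at 0.97 and 0.89 and Alas2 of haem synthesis at 0.89. This came with 1 array, since the erythroid array medians were -0.18 and 0.99 in VSKO. Without VSKO replicate 2 the erythroid median was 0.12 (adjusted p = 0.629), without VSKO replicate 1 it was 1.37 and without HEMI replicate 2 it was 0.85, and the call was also lost without HEMI replicate 1 (adjusted p = 0.127) or either WT array (adjusted p = 0.0608), with a range of 1.20e-07 to 0.629 over the alternatives. Gonocyte and spermatogonial stem cell genes went both ways, with a median of 0.04 (adjusted p = 0.147): adjusted over the list alone 6 of 21 fell, among them Nanos2, Zbtb16, Lin28b (-0.81) and Ret (-1.64), and 2 rose, Utf1 (0.77) and Dppa3 (1.34). Haploid spermatid genes had a median of 0.37 over 10 genes (adjusted p = 0.149), with 3 higher adjusted over the list alone, Ldhc (0.86), Akap4 (1.17) and Tnp1 (0.86). The hypoxia and glycolysis median was 0.09 (adjusted p = 0.666), that of Leydig cell genes 0.08 (0.903), steroid and cholesterol synthesis -0.12 (0.161), piRNA genes -0.07 (0.147), general germ cell genes -0.06 (0.233), ribosomal protein genes 0.12 (0.0948) and mesonephric genes -0.13 (0.233).

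The count of 35 was 14 without VSKO replicate 2 (10 of them among the 35) and 9 without HEMI replicate 1 (4 shared). It was 0 by limma without HEMI replicate 2, with 1692 genes at an unadjusted p under 0.05, and 0 without either WT array, with 1738. Among the 16 named genes that passed, Tekt1, Dkkl1, Spata21, Xkr6, Sall1 and others did so in none of the 6 fits. All 16 kept their direction, which their non-overlapping replicates fixed in advance. Of the 15 list calls in the 3 comparisons, 0 held in camera with an estimated correlation, and fry called 2. Median, mean and test differed in sign for gonocyte, macrophage, p53 target and circadian clock lists in more than 1 comparison, for the haploid spermatid list in HEMI against WT, and for the Sertoli, Leydig, myoid, imprinted, granulosa and SIN3 complex lists in VSKO against HEMI, none of which was called there.

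**Figure D2:**
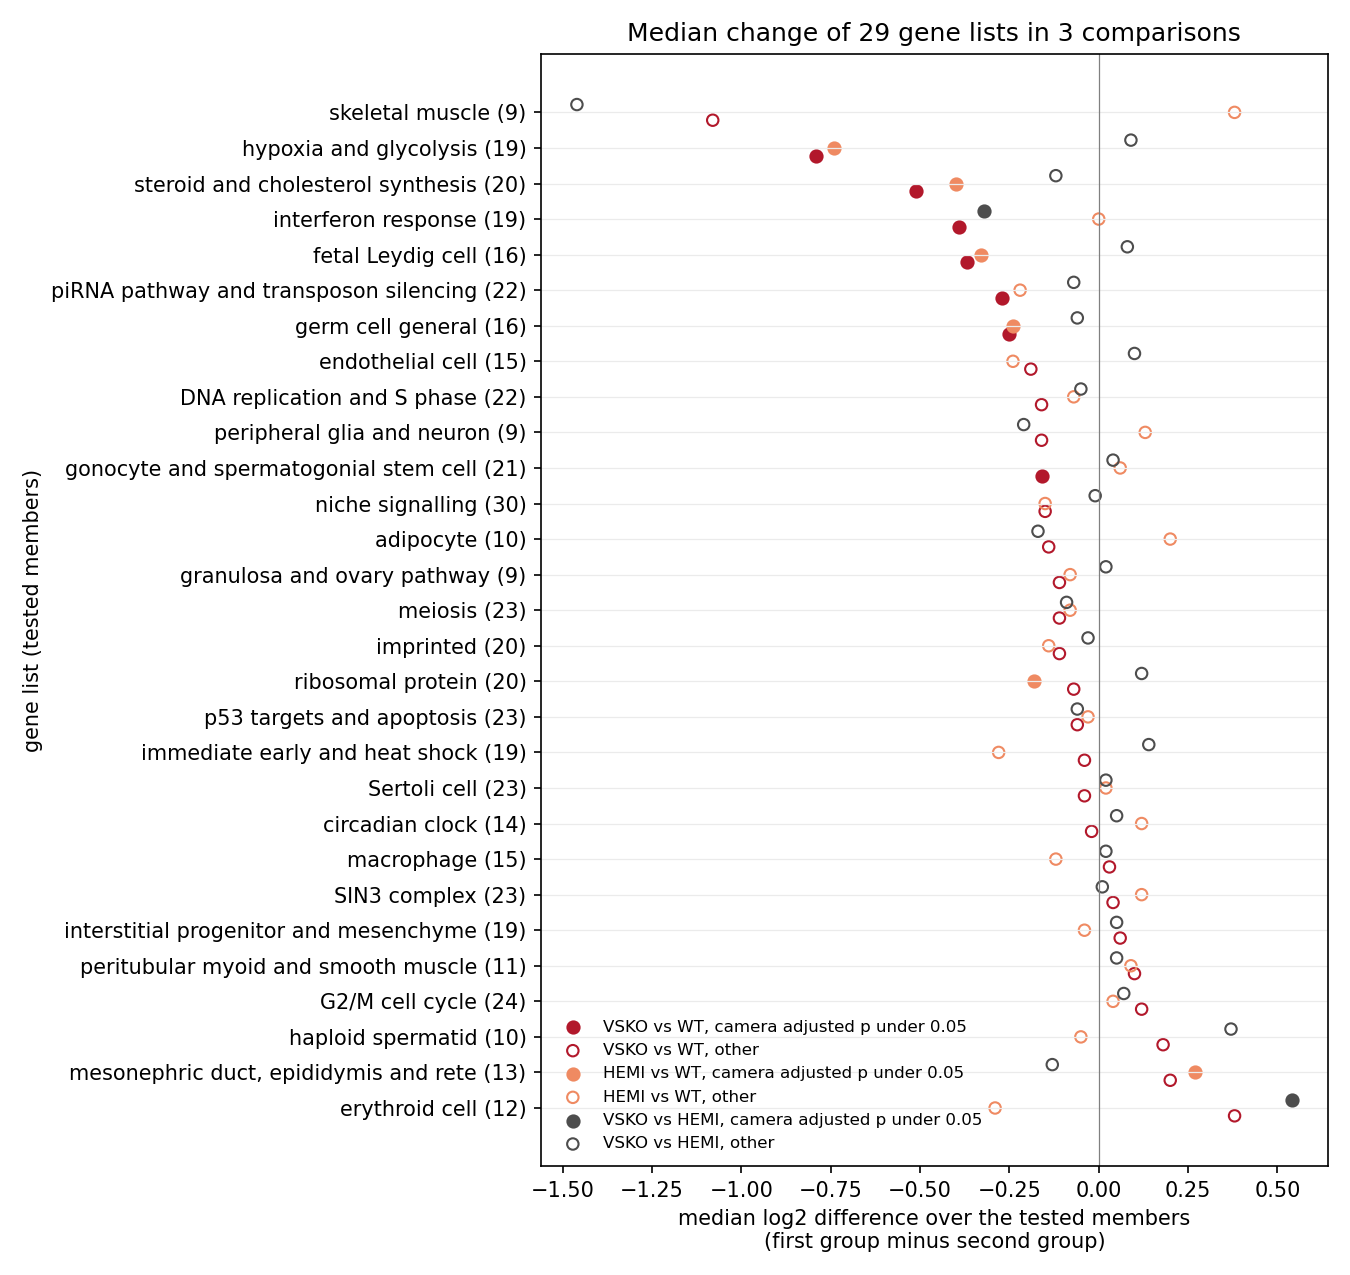
Median log2 difference over the tested members (horizontal axis) of each of 29 gene lists, with 1 point per comparison, filled where the camera adjusted p was under 0.05 at the preset correlation. The hypoxia and glycolysis list lies at -0.79 and -0.74 in the comparisons with WT and at 0.09 between VSKO and HEMI.

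VSKO and HEMI shared 24 genes changed against WT, 4 higher and 20 lower in both and 0 in opposite directions. They include Dnmt3l, Platr26, Mecom, Upp2, Olfr535, Olfr1317, Rbmy, Trim63 and Tacr3, which fell, and Krtap3-3 and Ankdd1a, which rose. Among them 11 carry no symbol, and 7 of these, well above background on all 6 arrays, were lower by -1.65 to -1.21 in VSKO and by -1.75 to -1.41 in HEMI, beside -1.63 to -1.32 and -1.68 to -1.43 for the 3 probes of Ldha. What these 7 probes measure was not settled here, and several may measure 1 transcript. Independent lists of these sizes would share 0.0277 higher and 0.130 lower genes, and simulated groups without a difference, in which hardly any gene passes, shared a mean of 0.01 and at most 1. At an unadjusted p under 0.05 the comparisons shared 1659 genes in direction, against a mean of 321 and at most 365 in the simulations and 84.5 higher and 141 lower for independent lists. The lists here held 3617 and 3054 genes, against the 1228 expected without a difference. Larger lists alone raise the overlap, so the simulations are no matched baseline. The covariance of the log2 differences was 0.152 against 0.0391 in the simulations. Noise in the simulations was independent between genes, so effects shared by many genes, such as those of litter or slide row, were not in it. The WT arrays are in both comparisons and cannot be split between them, so part of the excess may come from shared controls. The probes of Upp2, Mecom, Olfr535 and Olfr1317, well above background on the 2 WT arrays only, passed the filter through WT alone. That favours a fall in both groups, and the simulations did not repeat the filter. Without a single array the count was between 0 and 3: 2 without VSKO replicate 1 and 3 without VSKO replicate 2 (0 of them among the 24), 1 without HEMI replicate 1 (among the 24), and 0 by limma without HEMI replicate 2 or either WT array.

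VSKO differed the same way from both WT and HEMI in 25 genes, 21 higher and 4 lower, against a mean of 0.02 and at most 1 in the simulations, in which hardly any gene passes. At an unadjusted p under 0.05 they shared 980 genes in direction against a mean of 321 and at most 370 in the simulations, and the covariance was 0.140 against 0.0391. Here too the lists, of 3617 and 1888 genes, were larger than the 1228 expected without a difference, which alone raises the overlap. The probe of Slc29a4 and 1 probe without a symbol overlap in position, so the 25 lie at 24 loci. Independent lists would share 0.0865 higher and 0.0619 lower. They include Tekt1, Dkkl1, Xkr6, Hpcal4, Ssty1, Cacng2, Iqcf4, Olfr355 and Olfr429, which rose, and Sall1, Defb28 and Vmn1r132, which fell. The VSKO arrays are in both comparisons, so part of this excess may come from them, and noise shared between genes was not simulated. The probes of Hpcal4, Ssty1, Cacng2, Iqcf4, Olfr355 and Olfr429 were well above background on 2 arrays only, those of VSKO. Such probes passed the filter through VSKO alone, which favours a rise against both groups. The simulations did not repeat the filter, so they give no baseline for such genes. The count was 12 without VSKO replicate 2 (8 of them among the 25), 2 without HEMI replicate 1 (both among the 25), and 0 by limma without HEMI replicate 2 or either WT array.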

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

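The leave-one-out fits with a recomputed filter and all alternatives for the overlaps, except quantile scaling and an adjusted p under 0.1 for the overlap of VSKO and HEMI against WT, were chosen after the data were seen. The Sin3a differences kept their direction and their side of the threshold under each alternative run, and, leave-one-out aside, 1594 values of named genes were the same, 215 weaker, 53 stronger, 10 moved and 4 reversed, as were 1125, 42, 12, 39 and 0 of lists. In the order VSKO against WT (237 genes), HEMI against WT (29) and VSKO against HEMI (35), and where the count moved by over 1.5 times, no filter on dim probes gave 12, 0 and 5 (with 35052 genes tested), the filter on all 6 arrays 68 and 15 for the latter pair, only the 4 arrays of the groups compared 42, 4 and 0 (with fewer residual degrees of freedom), unadjusted p under 0.05 with 2-fold 1035, 663 and 581, and adjusted p under 0.1 gave 611, 166 and 121. Array weights gave 149 and 101 for the first pair, 55 and 74 came with median scaling and with the series values for the latter pair, quantile scaling 17 for VSKO against HEMI, and normexp 132 and a variance trend 130 for HEMI against WT; the cause was not tested. With replicate number as a block the counts were 19, 0 and 0, but the deviations of equal numbers correlated across genes at only -0.037 to -0.006 between groups, so the numbers do not pair the animals. By limma, 5278 of 35052 genes (no filter) and 2794 of 24553 (block) had an unadjusted p under 0.05 in HEMI against WT. In VSKO against HEMI there were 1738 (4 arrays) and 1872 (block), against 1228 expected with no difference. Leaving out 1 array on the same probes, with the lone array assumed to vary like the other groups, gave 0 to 69, 0 to 8 and 0 to 41 genes, 11 to 23 list calls (15 with all arrays), and 0 to 3 and 0 to 37 genes in the overlaps. With the filter recomputed, as first run, the ranges were 0 to 231, 0 to 146 and 0 to 172 genes and 0 to 137 and 0 to 148 in the overlaps, since a lone array lets more dim probes pass. List calls were 0 with an estimated correlation and 2 with fry. The overlap against WT (24) was 41 with median scaling and the series table, 104 with normexp, 0 with no filter, 56 with all 6 arrays above background, 0 with the block, 98 with a trend, 56 with weights, 368 at unadjusted p under 0.05 with 2-fold and 127 at adjusted p under 0.1. That of VSKO against WT and HEMI (25) was 11 with quantile scaling, 56 with median scaling and the series table, 3 with no filter, 11 with all 6 arrays above background, 0 with the block, 333 at unadjusted p under 0.05 with 2-fold and 87 at adjusted p under 0.1. With no filter, where another probe was the brightest, Iqcf4 turned to -0.63 against WT and -1.07 against HEMI, and Olfr965 to -0.38 in HEMI against WT and 0.63 in VSKO against HEMI. Without HEMI replicate 2 the macrophage list, not called with all arrays, turned to 0.54 in HEMI against WT (range over left-out arrays -0.59 to 0.54) and -0.45 in VSKO against HEMI (-0.45 to 0.56). Without HEMI replicate 1 the mesonephric list turned to -0.32 in HEMI against WT (-0.32 to 0.96), and the cause was not tested. Signal over background limits the 68, 12 and 18 changed genes that were dim in 1 group, for which only a lower bound of the fold can be given.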

Other observations

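The scan of gene families, the genes singled out here, and the tests of alleles near Sin3a (except for the whole set of genes higher in VSKO than in HEMI), of the mixed background, of Leydig cell number and of the share of germ cells were chosen after the results were seen. Among 272 gene families with at least 8 tested members, the Hoxb homeobox genes, which pattern the body axis, stood out: 10 of 10 were higher in VSKO than in WT, with a median log2 difference of 1.52 (camera adjusted p = 3.74e-06, and adjusted p = 0.996 with an estimated correlation). Against HEMI 10 of 10 were higher too, with a median of 1.01 (adjusted p = 3.54e-06, and adjusted p = 1 with an estimated correlation), and in HEMI against WT 8 of 10 were higher, with a median of 0.40 (adjusted p = 0.284). All 10 stayed higher in VSKO against both groups with quantile, median and series table scaling and with normexp correction, with medians of 1.14 to 1.52 against WT and 0.79 to 1.01 against HEMI. Of the 10, Hoxb1 alone passed, and Hoxb8 (3.26, adjusted p = 0.0513) and Hoxb4 (1.71, adjusted p = 0.0530) came close. The array medians of the cluster were 0.67 and 1.14 in VSKO, 0.18 and -0.54 in HEMI and -0.55 and -0.95 in WT. The other clusters lay near 0 against WT, with medians of -0.04 for Hoxa, 0.29 for Hoxc and 0.08 for Hoxd. The mesoderm gene T rose by 2.17 ± 0.26 (SE) in VSKO against WT (limma adjusted p = 0.0433) and did not pass against HEMI (1.44, adjusted p = 0.172). Cdx2, singled out as well, stood at 1.39 against WT and did not pass (adjusted p = 0.380), with 2 arrays well above background.

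Zscan4f, a gene of early embryos, stood at -2.65 and 1.94 on the VSKO arrays against -7.26 ± 0.74 (SD, n = 2) in HEMI and -6.97 ± 0.72 in WT, and did not pass against WT (adjusted p = 0.146). Ribosomal proteins of the large subunit had a median of -0.18 over 53 genes in HEMI against WT (adjusted p = 0.00803, and adjusted p = 0.957 with an estimated correlation). Asb and Fbxo genes, which encode adaptors of ubiquitin ligases, had medians of -0.33 over 14 and -0.09 over 34 genes in VSKO against HEMI (adjusted p = 0.00971 and 0.0369, and adjusted p = 1 for both with an estimated correlation).

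The 24 genes that changed the same way in VSKO and HEMI against WT, Dnmt3l, Platr26 and Krtap3-3 among them, had a median size of 2.14, and several of those without a symbol may measure 1 transcript. A shift of hybridisation common to all probes between the slide rows is argued against by the spike-in controls. These differed by at most 0.11 between WT and the other 4 arrays where above background, and by at most 0.32 where dim. Such controls cannot show an effect of slide row on particular probes, which stays open. Strain alleles linked to Sin3a cannot act in cis on the 22 genes on chromosomes other than 9, and their effects in trans were not tested; within 20 Mb of the Sin3a probe lay 4.35% of the genes with a position against 1.93% of all tested (one-sided Fisher's exact p = 0.361), which leaves open Ankdd1a, the 1 gene there, and 1 probe without a position. Strain alleles elsewhere in the mixed background may also contribute and were not decided by any test: a WT array overlapped the other 4 in 0 of the 24 genes, but the choice of these genes fixes that count. These alleles, litter or collection differences that follow slide row, and loss of 1 Sin3a allele, common to VSKO and HEMI, cannot be told apart here.

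Hypoxia and glycolysis genes were lower in VSKO and HEMI than in WT, by medians of -0.79 and -0.74. Drift of all genes of the same brightness is argued against by 10000 random lists matched on signal, whose lowest medians were -0.24 and -0.27, a share of 1e-04, the smallest they can give. The spike-in controls, at most 0.11 apart where above background, argue against a shift of hybridisation common to all probes between the slide rows. They cannot show an effect on particular probes. Fewer fetal Leydig cells, as the cause, were taken to lower Leydig cell genes at least as far as this list. The Leydig cell median lay 0.42 above that of this list in VSKO (95% bootstrap interval -0.43 to 0.75) and 0.40 above it in HEMI (-0.31 to 0.83). The intervals include 0, and the bootstrap resampled list members and not animals. The Leydig cell genes also differed widely among themselves. Star (-1.83 in VSKO and -1.94 in HEMI) and Cyp17a1 (-1.40 and -1.03) lay below the medians of the hypoxia and glycolysis list, while 2 of 16 were higher than in WT in each comparison. The gap between medians therefore decides nothing, and fewer Leydig cells may contribute. This explanation, time to dissection or oxygen supply of the litters, which were not recorded in the sources used here, and the loss of a Sin3a allele cannot be told apart.

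The 25 genes higher in VSKO than in HEMI, Tekt1, Dkkl1 and Xkr6 among them, had a median log2 difference of 2.28, and 21 of them also passed against WT. For 13 of them the probe was well above background on all 6 arrays, while noise near background stays open for the other 12, which were dim in HEMI. Those that were dim in WT too passed the filter through the VSKO arrays alone, which favours a rise against both groups. A higher share of germ cells in VSKO would raise germ cell genes alike, and their median was -0.06 with an SD of 0.43 over members and 1.19 at most, below the lowest of the 25 at 1.39. Strain alleles linked to Sin3a cannot act in cis on the 23 on chromosomes other than 9, while the 4% within 20 Mb of the Sin3a probe, against 1.93% of all tested genes (one-sided Fisher's exact p = 0.385), leaves open the 1 probe there, which has no symbol, with Iqcf4 on chromosome 9 outside that window, and trans effects of linked alleles and unlinked alleles of the mixed background were not tested for these genes. Loss of the second Sin3a allele in germ cells is a candidate explanation beside these, as a hypothesis found and tested on the same 6 arrays. With only the 4 arrays of VSKO and HEMI limma called 0 genes. At an unadjusted p under 0.05 there were 1738, against 1228 expected with no difference.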
